A study of Homo sapiens with 9 samples.

How the data were processed

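RNA was extracted with TRIzol and polyA RNA libraries were made with an NEBNext Ultra kit, per the labels. The 9 libraries came from Hep3B cells under hypoxia for 6 h, and groups and replicate numbers were taken from the sample titles: DMSO (n = 3) and DHE (n = 3) in a replicated set, and DMSO, DHE high and DHE low (1 library each) in a dose set. Each library has a table of RSEM gene results. The deposited tables hold the expected count of each gene, an estimated count that RSEM assigns from its reads and that is not normalized, per the file headers. They also hold TPM values, which the authors' RSEM run scaled for transcript length and library total, per the file headers. FPKM values were not used here. Transcripts carry RefSeq accessions, and the genome build is GRCh38, per the submitters' processing notes. The aligner, the versions of the tools and whether counting used strand are not given in the sources used here, so overlapping and antisense genes are uncertain, as are genes with near-identical copies.

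Symbols in the files are older in places, and 25637 of 26475 genes (96.8%) were matched by transcript accession to the RefSeq annotation of GRCh38.p14, which gave current symbols and coordinates. Expected counts were rounded to whole numbers. Library totals ranged from 22167516 to 36267216 counts, and the 3 counts that a count of 0 allows corresponded to 0.0827 to 0.135 CPM.

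DHE and DMSO of the replicated set were compared with edgeR 4.0.16 in R 4.3.3, with TMM factors, the default low-count filter by group and the two-sided quasi-likelihood F-test, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation was 8.37%. Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 25 lists with at least 5 tested genes, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. Of the 28 lists 5 passed upward and 3 downward at the preset correlation, and 2, HIF targets outside glycolysis and cholesterol synthesis, with the estimated one. The list of mitochondrial genome genes had no matched member and was not analysed here.

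In the dose set no test across genes was made. Log2 ratios of TMM-scaled CPM with a prior count of 2 were taken for genes with at least 20 counts in 1 of the 3 libraries. A list's median was placed among 10000 random lists of the same size matched on mean expression. Intervals of folds are exact binomial intervals of the counts at 95%. Unchanged libraries against the shared control were simulated 50 times, with the spread between libraries of the replicated set. An edgeR fit over all 9 libraries had the set as a covariate.

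The genes named are 15 HIF-related and deiminase genes; the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap; up to 4 members per list with the smallest p; and in the dose set the 5 highest and 5 lowest of the same sign at both labelled doses with at least 100 counts in a library. Exceptions are said to have been chosen after their values were seen. Some genes that the rule names are not reported here. Alternatives included DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), other scaling factors and filters, leaving out each library, and the replicate number as a block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

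The edgeR comparison was tested on simulated counts for 14492 genes with 50 genes changed at each of 4 fold sizes, and recovered 58% at 1.3-fold, 66% at 1.5-fold, 86% at 2-fold and 92% at 3-fold. Of 165 calls 14 were false (8.48%). In a simulation of camera the list that was shifted was called and none of the others was. Its genes were drawn independently, so it says nothing on false calls of lists whose genes vary together. The estimated inter-gene correlation of the measured lists reached 0.476 for heat shock and 0.742 for ribosomal protein genes. In the simulated dose set, which had counting error only, 100 of 100 changed genes reached 2-fold, with 15 of the other genes. The changed genes were picked among well counted genes and had a median log2 ratio of 2.01. Their recovery was thus nearly fixed in advance and says nothing on smaller changes or on spread between cultures.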

Results

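Gene expression was measured by RNA sequencing of polyA RNA from Hep3B, an established human liver cancer line, kept under hypoxia for 6 h with DMSO, the solvent control, or with a compound labelled DHE. The series title concerns citrullination and the stabilisation of HIF-1A, the oxygen-regulated subunit of the hypoxia-inducible transcription factor, and the comparison asks how DHE alters transcription in hypoxic liver cancer cells. The 9 libraries form a replicated set, with 3 DMSO and 3 DHE libraries, and a dose set, with 1 library each for DMSO, DHE at a dose labelled high and DHE at a dose labelled low. The labels give no concentration for either set. The DMSO replicates held 33563425, 35590005 and 36267216 counts and the DHE replicates 26997899, 31329105 and 33962591. In the dose set the DMSO library held 26956140 counts, the library labelled high 25508263 and the library labelled low 22167516. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

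The genes for peptidylarginine deiminases, the enzymes that convert arginine in proteins to citrulline, were at or near the limit of detection. PADI4 had 1 count in DMSO replicate 3 and 0 in the other 8 libraries, where a count of 0 allows up to 0.0843 to 0.135 CPM (counts scaled to the library total), depending on the library. PADI2 had at most 18 counts in a library, PADI1 at most 4, and PADI3 and PADI6 at most 1. None of these 5 genes passed the filter on low counts, so no change was tested for them.

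DHE lowered many targets of the hypoxia-inducible factor in the replicated set, while the transcript of HIF1A itself rose. NDRG1, a stress-response gene induced by hypoxia, fell 1.59-fold, from 1311 ± 36.5 CPM in DMSO to 825 ± 20.4 CPM in DHE (SD, n = 3 each), with a log2 fold change of -0.67 ± 0.05 (SE) and an adjusted p = 3.47e-06 by edgeR. EPO, the erythropoietin gene, fell 1.68-fold (-0.75 ± 0.13, edgeR adjusted p = 0.00134). HIF1A rose 1.23-fold, from 123 ± 3.65 to 152 ± 4.21 CPM (0.30 ± 0.05, edgeR adjusted p = 7.34e-04). In GRCh38, NDRG1 lies on chromosome 8 from 133237175 to 133297252 and HIF1A on chromosome 14 from 61695513 to 61748258.

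Of the HIF genes and targets singled out before the data were examined, 13 could be tested, and 1 rose and 7 fell. Adjusted over the list alone, 1 rose and 9 fell. ADM, the gene for the vasodilator peptide adrenomedullin, fell 1.40-fold, VEGFA, the main growth factor of blood vessels, 1.34-fold, CA9, a cell-surface carbonic anhydrase, 1.27-fold, and PDK1, a kinase that restrains the entry of pyruvate into mitochondrial oxidation, 1.21-fold. The genes that did not pass edgeR's threshold were EPAS1, the HIF-2 alpha gene (-0.14, adjusted p = 0.0654), SLC2A1 (-0.14, adjusted p = 0.117), LDHA (0.11, adjusted p = 0.178), PGK1 (-0.13, adjusted p = 0.0695) and BNIP3 (-0.05, adjusted p = 0.627). On a log2(TPM + 1) scale with limma, HIF1A (adjusted p = 0.0815), VEGFA (adjusted p = 0.0587), CA9 (adjusted p = 0.0672) and PDK1 (adjusted p = 0.248) did not pass the threshold.

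**Figure D1:**
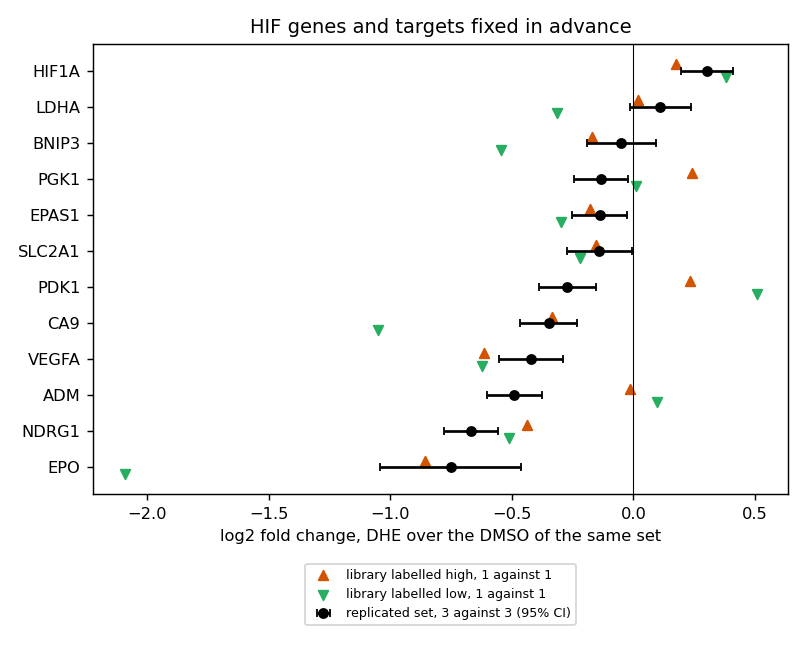
Log2 fold change of DHE over the DMSO libraries of the same set (horizontal axis) for the HIF genes and targets singled out in advance and reported here (vertical axis), with the replicated set as black points with 95% confidence intervals and the single libraries labelled high and low as triangles. In the replicated set NDRG1 lies at -0.67 and HIF1A at 0.30.

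HIF targets outside glycolysis fell as a group in the replicated set. Of 40 tested members 23 fell and 4 rose, with a median log2 fold change of -0.24 (camera adjusted p = 7.44e-11, and adjusted p = 0.0324 with an estimated correlation). Adjusted over the list alone, 24 fell and 9 rose. Leaving out each library in turn gave 21 to 23 lower and 1 to 5 higher, the latter 1 without DMSO replicate 1, DMSO replicate 2, DMSO replicate 3 or DHE replicate 3. ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell 2.08-fold from 181 ± 7.15 to 86.9 ± 4.52 CPM (SD, n = 3 each), and LOX, an enzyme that crosslinks collagen, fell 1.49-fold. Targets in glucose uptake and glycolysis did not pass as a set by camera, though fry called them lower (fry adjusted p = 0.0146). Of 23 tested, 6 fell and 1 rose, or 9 and 2 adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.309). The member that rose was PFKFB3, a regulator of glycolytic flux, at 0.61. Of 16 tested components of the HIF pathway 5 rose and 2 fell, or 6 and 3 adjusted over the list alone (median 0.04, camera adjusted p = 0.665). CITED2, a HIF-induced competitor for the coactivators of HIF, fell 1.56-fold and HIF3A 1.56-fold.

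Genes of cholesterol synthesis rose together. Of 25 tested members 21 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 0.38 (camera adjusted p = 5.95e-15, and adjusted p = 0.0497 with an estimated correlation). CYP51A1, the sterol 14-demethylase, rose 1.54-fold from 98.5 ± 4.02 to 151 ± 9.86 CPM (SD, n = 3 each), and ACAT2, which makes acetoacetyl-CoA, 1.52-fold. Without DMSO replicate 1, 20 members of this list were higher and 1 lower. In fatty acid synthesis 7 rose and 0 fell of 16 members, also when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.00187, and adjusted p = 0.190 with an estimated correlation). The desaturase genes FADS2 and SCD rose 1.5-fold and 1.39-fold.

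Heat shock genes rose as well, with 9 of 15 members higher and 0 lower, or 10 and 0 adjusted over the list alone. Their median was 0.37 (camera adjusted p = 3.49e-14, and adjusted p = 0.190 with an estimated correlation). HSPA8, the constitutive HSP70 chaperone, rose 1.74-fold from 495 ± 8.29 to 863 ± 25.9 CPM (SD, n = 3 each), HSPH1, an HSP110 chaperone, 1.78-fold, and DNAJB1, a cochaperone of HSP70, 1.5-fold. Chaperones of the endoplasmic reticulum did not pass as a set by camera: 6 fell and 2 rose of 20 (median -0.06, camera adjusted p = 0.133). Without DHE replicate 1 that list passed (adjusted p = 0.0257), as it did without both number-1 libraries (adjusted p = 0.0286, within a range of 0.0257 to 0.587 over its alternatives).

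Transcription factors of hepatocyte identity rose in the replicated set, with 7 of 15 higher and 3 lower, or 9 and 4 adjusted over the list alone. Their median was 0.25 (camera adjusted p = 0.0118, and adjusted p = 0.294 with an estimated correlation). HNF4A, a master regulator of liver genes, rose 1.42-fold from 239 ± 2.36 to 340 ± 15.2 CPM (SD, n = 3 each) and PROX1, a homeobox gene of the liver, 1.35-fold. Genes for proteins that hepatocytes secrete moved both ways and did not pass as a set. Of 24 tested, 9 rose and 8 fell, or 9 and 9 adjusted over the list alone (median 0.11, camera adjusted p = 0.306). The fibrinogen genes FGA and FGB rose 1.59-fold and 1.65-fold and the vitronectin gene VTN 1.43-fold, whereas ALB, the albumin gene, and AFP, the alpha-fetoprotein gene, fell 1.25-fold and 1.22-fold. ALB and AFP were singled out after their values were seen.

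Transcripts of replication-dependent histone genes, which mostly lack a polyA tail, were higher in all 3 DHE libraries, with a sum of 180, 164 and 162 CPM against 112, 99.8 and 105 CPM with DMSO. Of 12 tested genes 4 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median of 0.79 (camera adjusted p = 0.00391, and adjusted p = 0.239 with an estimated correlation). Without DMSO replicate 3, 2 genes were called, since HIST1H1C (edgeR adjusted p = 0.146) and HIST1H4H (adjusted p = 0.0729) lost their calls. HIST1H2BK, now named H2BC12, rose 1.59-fold and HIST1H2BD, now H2BC5, 1.79-fold, though histone genes are close copies and reads may be split between them. Their means went from 62.2 to 99.0 CPM and from 22.3 to 39.8 CPM. The sums thus rest mostly on these 2 genes and say little on the others. Ribosomal RNA took 1.58 ± 0.537% of counts in DMSO and 1.5 ± 0.912% in DHE (SD, n = 3 each), with the highest shares in DMSO replicate 1 (2.18%) and DHE replicate 1 (2.55%).

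Of 14 leukocyte markers 7 could be tested, and 3 fell while none rose, also when adjusted over the list alone (median -0.40, camera adjusted p = 0.00125, and adjusted p = 0.190 with an estimated correlation). CD68, a lysosomal glycoprotein used as a macrophage marker, fell 2.13-fold from 63.0 ± 2.23 to 29.5 ± 0.417 CPM (SD, n = 3 each). Of 13 fibroblast and stellate markers 6 could be tested, and 2 were called higher (median 0.22, camera adjusted p = 0.133), the collagen gene COL1A1 at 0.37 and PDGFRA at 0.30. The edgeR call of PDGFRA ended without DMSO replicate 3 (adjusted p = 0.0768) and without DHE replicate 2 (adjusted p = 0.0798). Of 12 endothelial markers 2 could be tested, too few for a set test. Of these PECAM1 was lower at -0.92 (edgeR adjusted p = 0.0133), a call that ended without DMSO replicate 1 (adjusted p = 0.0575), DMSO replicate 3 (adjusted p = 0.0590) or DHE replicate 3 (adjusted p = 0.0502).

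Ribosomal protein genes fell slightly as a set, with 6 of 38 lower and 0 higher, or 4 and 0 adjusted over the list alone (median -0.12, camera adjusted p = 0.0180, and adjusted p = 0.668 with an estimated correlation). RPL3, of the large subunit, fell 1.24-fold. Without DHE replicate 1, 34 of these genes were lower, and without another library 2 to 4. The set call ended without DMSO replicate 1 (camera adjusted p = 0.109), DHE replicate 2 (adjusted p = 0.232) or DHE replicate 3 (adjusted p = 0.232), within a range of 4.23e-12 to 0.668 over its alternatives. For oxidative phosphorylation 5 fell and 0 rose of 32 (median -0.08, camera adjusted p = 0.0532), among them NDUFV1, of complex I, by 1.26-fold. That list passed without DMSO replicate 2 (camera adjusted p = 0.0264) and without DHE replicate 1 (adjusted p = 9.20e-05, with 15 genes lower). It also passed with no filter on low counts (adjusted p = 0.0349) and with the replicate number as a block (adjusted p = 0.0215). Without both number-1 libraries, a setting chosen after the data had been seen, it passed as well (adjusted p = 1.04e-04). The range was 9.20e-05 to 0.659. For genes of G2 and M phase 7 fell and 1 rose of 26 (median -0.04, camera adjusted p = 0.119), with the kinesin gene CENPE 1.57-fold lower. Without DHE replicate 1 this list passed (adjusted p = 0.0409, within a range of 0.0409 to 0.441).

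The other lists did not pass as sets by camera. Fry called DNA replication (fry adjusted p = 6.09e-04), p53 targets (0.0314) and epithelial and mesenchymal genes (0.00141) higher. Genes of the integrated stress response driven by ATF4 moved both ways (7 rose and 7 fell of 30, median -0.01, camera adjusted p = 0.978). NUPR1, a stress-induced chromatin protein gene, rose 1.60-fold, while DDIT4, an inhibitor of mTORC1, fell 1.35-fold and the lipoprotein receptor gene VLDLR 1.71-fold. In DNA replication 9 rose and 4 fell of 30 (median 0.07, camera adjusted p = 0.133), with CLSPN, a checkpoint adaptor gene, at 0.47. Of p53 targets 4 rose and 3 fell of 20 (median 0.08, camera adjusted p = 0.351), with TP53INP1 at 0.60 and GADD45A at -0.74. Of NRF2 targets 2 rose and 4 fell of 21 (median -0.06, camera adjusted p = 0.474), with PGD, of the pentose phosphate pathway, at 0.38. Immediate early genes went both ways (5 rose and 6 fell of 26, median -0.08, camera adjusted p = 0.474), with the kinase gene SGK1 at 1.12 and ZFP36, which destabilises inflammatory mRNAs, at -0.57. Of inflammatory NF-kB targets 3 rose and 4 fell of 16 (median 0.02, camera adjusted p = 0.665), with CXCL8, the interleukin-8 gene, at 0.83 and the chemokine gene CCL20 at -0.36. Of lysosome and autophagy genes 9 rose and 5 fell of 30 (median 0.06, camera adjusted p = 0.419), with the sialidase gene NEU1 at 0.39.

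Interferon response genes (1 higher and 1 lower of 17, median -0.08, camera adjusted p = 0.419) included IRF9 at 0.35 and OAS1 at -0.91. The edgeR call of OAS1 ended without DMSO replicate 1 (adjusted p = 0.0524), and that of IRF9 without DMSO replicate 1 (adjusted p = 0.0950), DMSO replicate 3 (adjusted p = 0.0933), DHE replicate 1 (adjusted p = 0.0615) or DHE replicate 2 (adjusted p = 0.0802). Genes of the AHR and xenobiotic metabolism (3 rose and 5 fell of 18, median 0.21, camera adjusted p = 0.978) included the cytochrome gene CYP1A1 at -0.48 and the drug efflux gene ABCB1 at 0.36. Epithelial and mesenchymal genes (4 rose and 3 fell of 19, median 0.04, camera adjusted p = 0.345) included the N-cadherin gene CDH2 at 0.45 and the E-cadherin gene CDH1 at -0.29. Leaving out each library in turn gave 0 to 1 higher and 3 to 7 lower for chaperones of the endoplasmic reticulum, 6 to 8 and 0 to 3 for DNA replication, 3 to 4 and 1 to 2 for p53 targets, 1 to 2 and 2 to 4 for NRF2 targets, 2 to 3 and 2 to 3 for NF-kB targets, 5 to 10 and 2 to 4 for lysosome and autophagy genes, 1 to 3 and 3 to 4 for the AHR list, and 0 to 1 and 0 to 2 for interferon response genes. It gave 3 to 9 lower for G2 and M phase and 1 to 2 higher for glycolysis. Adjusted over the list alone, the counts of the lists that did not pass, glycolysis apart, moved by at most 1 gene in either direction.

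**Figure D2:**
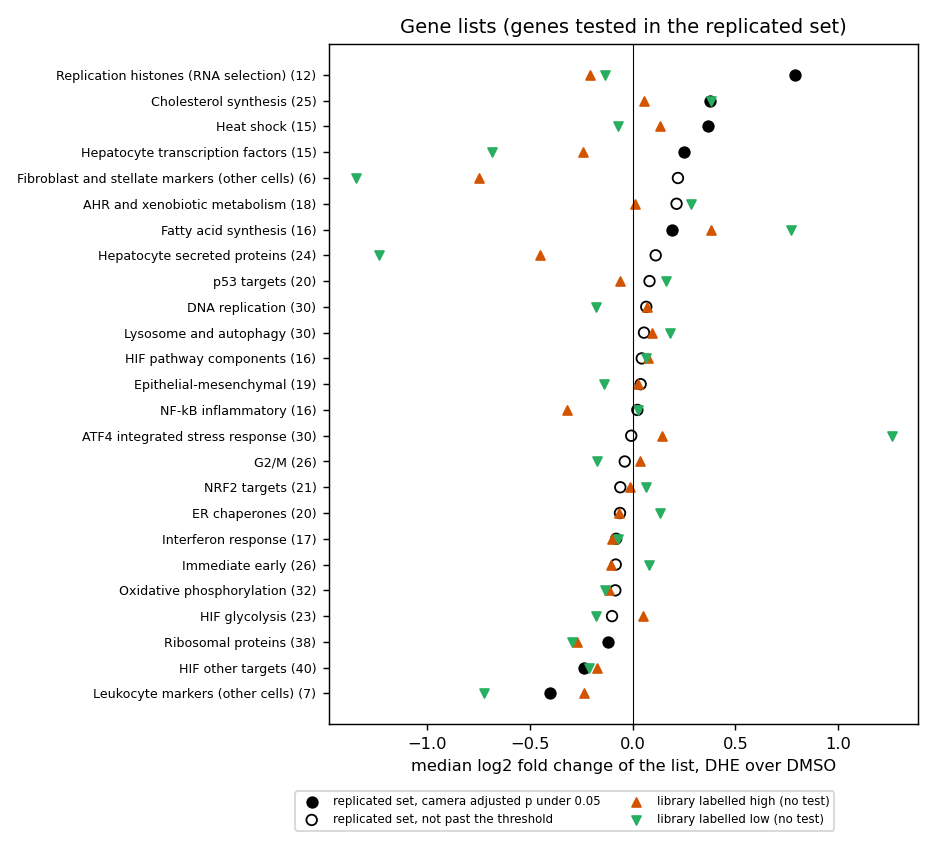
Median log2 fold change of DHE over DMSO (horizontal axis) of each gene list with at least 5 tested genes, given with their number (vertical axis). The replicated set is shown as circles, filled where camera's adjusted p is under 0.05, and the single libraries labelled high and low as triangles. Histone genes have the highest median of the replicated set (0.79) and leukocyte markers the lowest (-0.40). Of the lists with a dose-set median beyond the spread between replicated libraries, 6 change sign under another scaling or unit.

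Among the genes with the largest changes, THBS1, the gene for the matrix glycoprotein thrombospondin-1 on chromosome 15 from 39581079 to 39599466, rose 2.51-fold from 307 ± 3.55 to 771 ± 42.3 CPM (SD, n = 3 each, log2 fold change 1.33 ± 0.05, edgeR adjusted p = 2.92e-08). FLRT2, a leucine-rich transmembrane protein gene on chromosome 14 from 85530144 to 85654428, rose 2.71-fold from 99.1 ± 2.41 to 269 ± 3.36 CPM (1.44 ± 0.05, edgeR adjusted p = 3.62e-09). NRP2, a coreceptor for semaphorins and VEGF ligands, rose 3.16-fold, the protocadherin gene PCDH9 2.92-fold, CER1, a secreted antagonist of NODAL and BMP signals, 2.75-fold, the adhesion receptor gene ADGRF2 2.58-fold, the tubulin gene TUBA1A 2.41-fold and the metallothionein gene MT2A 2.36-fold. TUBA1A and MT2A have close copies, so reads may be split between family members. TMC8, on chromosome 17 from 78130771 to 78142968, fell 3.21-fold from 51.5 ± 1.14 to 16 ± 2.04 CPM (-1.68 ± 0.09, edgeR adjusted p = 1.84e-07). RASL11A, a small GTPase gene, fell 3.56-fold, the glutamate transporter gene SLC1A7 2.74-fold, the pseudogene FER1L4 2.73-fold, CDC42EP5 2.65-fold, the circadian repressor gene BHLHE41 2.58-fold, the fatty acid transport gene SLC27A1 2.50-fold and BAIAP2L2 2.47-fold.

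In all, 1945 of 14492 tested genes rose and 1858 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Most changes were small, with a median absolute log2 fold change of 0.347 among called genes, and 69 were at least 2-fold higher and 167 lower. The groups did not overlap in 41.6% of tested genes, where chance gives 10% for 3 against 3. DHE replicate 1 stood apart from DHE replicates 2 and 3, by 30.9 and 36.4 chi-square units per gene, where these differed by 5.83, and without it 3980 genes were called. Limma on log2(TPM + 1) called 964 genes, and those described above that did not pass there, the HIF genes already given apart, were ABCB1 (adjusted p = 0.0908), CDH1 (adjusted p = 0.167), CLSPN (adjusted p = 0.0956), COL1A1 (adjusted p = 0.101), IRF9 (adjusted p = 0.101), NDUFV1 (adjusted p = 0.0703), PDGFRA (adjusted p = 0.280) and RPL3 (adjusted p = 0.0733).

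**Figure D3:**
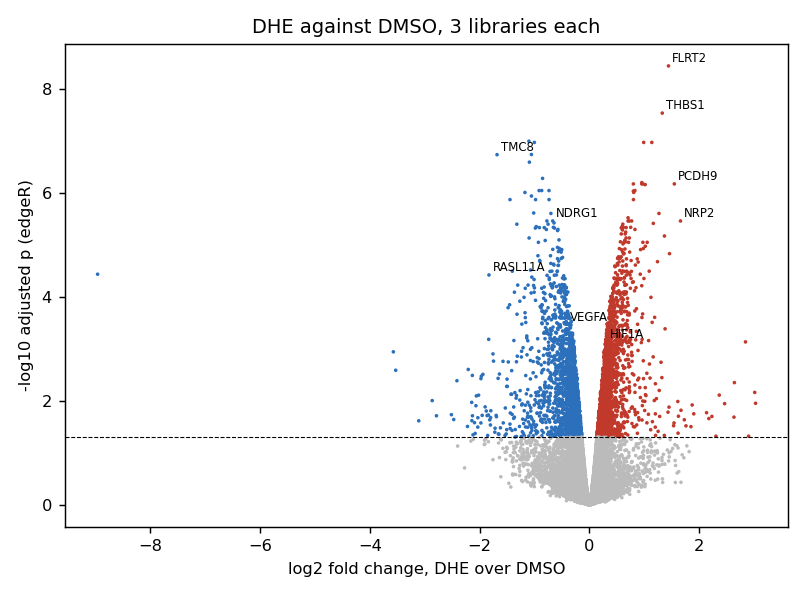
Log2 fold change of DHE over DMSO (horizontal axis) against the minus log10 of edgeR's adjusted p (vertical axis) for 14492 genes, 3 libraries per group. Red points rose and blue points fell past the threshold drawn as a dashed line, grey points did not pass it, and FLRT2 has an adjusted p = 3.62e-09.

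In the dose set both DHE libraries held less mRNA of hepatocyte genes than the DMSO library, the library labelled low more so. ALB was 2.57-fold lower in the library labelled high (95% exact binomial interval 2.55 to 2.58) and 5.01-fold lower in that labelled low (4.98 to 5.04), from 28029 CPM with DMSO. AFP was 3.10-fold and 8.18-fold lower. Scaled over all 9 libraries, AFP stood at 2613 CPM with DMSO, 848 for high and 318 for low. The DMSO replicates of the other set held 182.3, 177.8 and 177.5 CPM of AFP. ALB stood at 5903 CPM for low, near the 6372, 5829 and 5982 CPM of the DMSO replicates. These falls thus rest on 1 DMSO library that held more ALB and AFP than the DMSO replicates. Of 24 genes for secreted proteins 7 were at least 2-fold lower in the library labelled high and 15 in that labelled low, with median log2 ratios of -0.45 and -1.24, both below all 10000 random lists of matched expression. The hepatocyte transcription factors had medians of -0.24 and -0.68, at percentiles 0.06 and 0. With 1 library per group there is no replicate check, and intervals and floors cover counting error only.

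The library labelled low held more mRNA of the integrated stress response. Of 31 ATF4 list genes 19 were at least 2-fold higher there, with a median of 1.26 (percentile 100), against 1 gene and a median of 0.14 (percentile 98.8) in the library labelled high. ASNS, asparagine synthetase, was 1.60-fold higher for high and 3.67-fold for low, and TRIB3, a stress-induced pseudokinase gene, 1.39-fold and 2.66-fold. The fatty acid synthesis list had medians of 0.38 and 0.77, at percentiles 100 and 100, and FASN, the fatty acid synthase gene, was 1.33-fold and 1.88-fold higher. ASNS, TRIB3 and FASN were chosen as examples after their values were seen. The cholesterol list had medians of 0.06 and 0.38 (percentiles 89.3 and 100), and the heat shock list of 0.13 and -0.07 (percentiles 94.2 and 31.8).

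HIF targets outside glycolysis were lower in both DHE libraries, with medians of -0.17 for high and -0.21 for low, at percentiles 0.05 and 0.835. The size of these medians depends on the scaling, since library size only raised the median of all genes by 0.0646 and 0.133, towards smaller falls. VEGFA was 1.53-fold lower for high and 1.54-fold for low, EPO 1.81-fold and 4.29-fold, CA9 1.26-fold and 2.07-fold, and LOX 1.87-fold and 3.58-fold. ADM had log2 ratios of -0.01 and 0.10, PDK1 of 0.23 and 0.51, and HIF1A of 0.17 and 0.38. The glycolysis list had medians of 0.05 and -0.18 (percentiles 81.2 and 12.1), and ribosomal protein genes of -0.27 and -0.29 (percentiles 0 and 0.71).

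The genes with the largest shifts of the same sign in both libraries were led, on the lower side, by HAMP, the gene for the iron hormone hepcidin. HAMP had 171 counts with DMSO, 4 in the library labelled high and 0 in that labelled low. It was thus 42.3-fold lower (95% exact binomial interval 16.2 to 157) for high and at least 51.4-fold lower for low, against a floor of 3 counts in that library. The exact binomial interval, which also covers the counting error of the DMSO library, has a lower bound of 41.4-fold there. Scaled over all 9 libraries, HAMP stood at 7.045 CPM in this DMSO library but at 0.0587, 0.245 and 0.4 CPM in the DMSO replicates. The fall of HAMP thus rests on 1 control library that differed from the other controls. KNG1, the kininogen gene, was 5.60-fold and 20.7-fold lower, EDNRB, an endothelin receptor gene, 9.49-fold and 10.4-fold, ATOH8, a transcription factor gene, 6.09-fold and 10.1-fold, and PLAC8 6.62-fold and 7.43-fold. On the upper side the phospholipase gene PLA2G3 was 4.04-fold and 17.8-fold higher, BEST1 5.25-fold (interval 1.98 to 17.5) and 23.3-fold (9.66 to 73.2), ARHGAP40 3.55-fold and 7.05-fold, and the glutamate receptor gene GRIK2 3.26-fold and 5.16-fold. The read-through BIVM-ERCC5 had 0, 16 and 247 counts with DMSO, high and low, and is uncertain because it shares reads with the genes it joins.

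Of 13468 genes, 127 were at least 2-fold higher and 456 lower in the library labelled high, and 408 and 889 in that labelled low. Counts simulated without any effect, with the spread of the replicated libraries, gave 198 and 207 such genes. That spread may be technical and is not from the dose set, so these counts and the simulated covariance below may be too low. Of the measured genes past 2-fold, 21.8% were higher for high and 31.5% for low. With scaling by library size only, 27.3% and 43.9% were higher. That scaling moved the median of all genes by 0.0646 and 0.133 on the log2 scale. Both libraries shared 95 genes higher and 314 lower, where independent lists would share 3.85 and 30.1. Across genes, which are not independent replicates, their log2 ratios correlated at 0.745, against 0.495 for simulated libraries without an effect, and their covariance was 0.235 against 0.0466, a difference of 0.188. Part of the overlap may come from the shared DMSO library, which cannot be split. Set against each other, 280 genes were at least 2-fold higher and 227 lower in the library labelled high than in that labelled low, and the ATF4 list had a median ratio of -1.03 and the secreted protein list of 0.74 (percentiles 0 and 100).

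**Figure D4:**
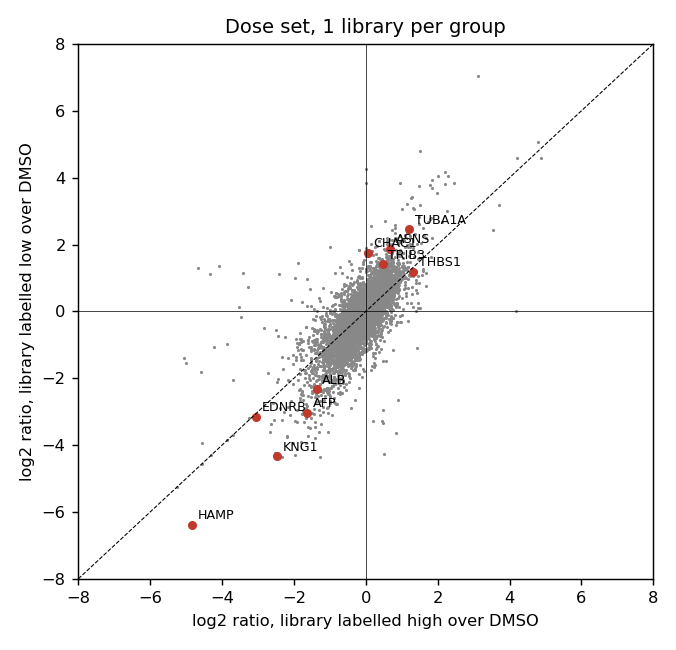
Log2 ratio to the DMSO library of the dose set in the library labelled high (horizontal axis) and in the library labelled low (vertical axis), each point a gene measured in single libraries and the dashed line marking equal ratios. ALB lies at -1.36 and -2.32 and ASNS at 0.67 and 1.87.

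Genes called in the replicated set mostly had the same sign in the dose set, which shares no library with it. THBS1 had log2 ratios of 1.32 for high and 1.18 for low, TUBA1A of 1.21 and 2.45, and RASL11A of -2.18 and -3.74, whereas FLRT2 had 0.15 and -0.52 and ADGRF2 -1.11 and -1.78. Of 1909 genes called higher, 80.5% (95% exact binomial interval 78.6 to 82.2) were higher for high and 72.1% (70.0 to 74.1) for low. Of all 13285 genes, 51.9% and 51.6% had that sign. Of 1792 called lower, 78.5% (76.5 to 80.4) and 74.3% (72.2 to 76.3) were lower, against 48.1% and 48.4%. The intervals count genes as independent, which they are not, and do not measure the spread between libraries.

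An edgeR fit over all 9 libraries with the set as a covariate, pooling both labelled doses as DHE, called 1401 genes higher and 1366 lower, and 2413 of these were also called in the replicated set, all with the same sign. VEGFA (log2 fold change -0.49), HIF1A (0.30), THBS1 (1.3) and CYP51A1 (0.58) passed there. Of 126 genes named by rule, 30 lost their call, and 2 that had been called in the replicated set changed sign. By their edgeR adjusted p in that fit, those described above that lost it were ADGRF2 (0.582), BHLHE41 (0.0995), COL1A1 (0.666), CYP1A1 (0.790), FGA (0.560), FGB (0.432), HIST1H1C (0.7175), HIST1H2BD (0.149), HNF4A (0.178), IRF9 (0.0883), OAS1 (0.108), PDGFRA (0.946), PDK1 (0.622), PFKFB3 (0.144), PROX1 (0.0521), SGK1 (0.203), VLDLR (0.0672) and VTN (0.677).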

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

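The tests of a difference between the sets, and the tests of HIF1A mRNA, of the most abundant genes, of other cell types and of the control libraries, were chosen after the results they concern had been seen. Thinning, RLE factors and leaving out both number-1 libraries were added after the data had been seen.

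The effect of DHE differed between the replicated set and the dose set for 10 lists at camera's preset correlation, in a fit that treats both labelled doses as replicates and assumes that the lone DMSO library of the dose set varies like the others. None of the 10 passed with an estimated correlation, where their adjusted p lay between 0.158 and 0.871. The median difference in log2 fold change, replicated set minus dose set, was 0.97 for hepatocyte secreted proteins (camera adjusted p = 1.06e-15), 0.53 for hepatocyte transcription factors (adjusted p = 8.20e-08), -0.74 for the ATF4 stress response (adjusted p = 1.61e-09) and 0.43 for heat shock genes (adjusted p = 3.76e-09). It was -0.34 for fatty acid synthesis (adjusted p = 4.44e-04), 0.24 for NF-kB targets (adjusted p = 9.42e-04), 0.18 for ribosomal proteins (adjusted p = 0.00485) and 0.19 for epithelial and mesenchymal genes (adjusted p = 0.0118). For replication histones it was 1.2 (adjusted p = 0.00103) and for fibroblast markers 1.36 (adjusted p = 8.41e-05). The HIF targets outside glycolysis differed by 0.08 (adjusted p = 0.969), which did not pass. Of 15531 genes 324 passed edgeR's test of the difference.

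Hepatocyte genes moved apart between the sets, and the control libraries already differed. The secreted protein list was 1.11 higher on the log2 scale in the DMSO library of the dose set than in the DMSO replicates. It was higher for 20 of 24 genes, with a 95% interval of 0.60 to 1.76 by a bootstrap over the genes. With 1 such library, that interval measures the spread between genes and not between libraries. The tables argue against a few abundant genes setting the scale, which moved it by at most 0.0653. Markers of leukocytes, fibroblasts and endothelium had medians of -0.50 for high and -0.77 for low in the DHE libraries of the dose set. The collagen gene COL1A1 stood at 3.89 CPM with DMSO, 1.80 for high and 1.98 for low, and CD74 at 24.9, 16.9 and 11.8. These values cannot decide on a gain of other cells, since the cell line may itself express such markers. The markers did not move alike, since LUM was 1.45-fold and 2.63-fold higher (interval 2.35 to 2.94 for low) and CD3D was higher at log2 ratios of 0.32 and 1.41, and in the replicated set COL1A1 and PDGFRA were higher (0.37 and 0.30); the cause was not tested. Another state of the cells before treatment may contribute, and a difference in dose, which the labels do not give, or in library preparation stays open and untested, where the mean fragment length, estimated from gene length minus effective length, was 262 to 264 bases in the dose set and 290 to 326 in the replicated set.

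HIF targets outside glycolysis were lower after DHE. A trend with gene length is argued against, since the list's median after its removal was -0.22, with an upper 95% bound of -0.0537 by a bootstrap over its genes. Without both number-1 libraries, which held the most ribosomal RNA in the replicated set, the median was -0.23 (camera adjusted p = 7.53e-13). Less HIF1A mRNA is argued against by a log2 fold change of 0.30 for that gene. This does not cover EPAS1, the HIF-2 alpha gene, at -0.14 in the replicated set (edgeR adjusted p = 0.0654). Its log2 ratios in the dose set were -0.18 for high and -0.30 for low. Less EPAS1 mRNA stays open and was not tested as an explanation. Lower activity of the factor at the protein level may be an explanation, and neither it nor GC content was tested here.

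More genes passed 2-fold in the library labelled low than in that labelled high, by a ratio of 2.22, which became 3.28 with a minimum of 100 counts and 4.50 on log2(TPM + 1). Lower depth is argued against by a ratio of 2.19 with the libraries thinned to the same total, and scaling by a smallest ratio of 2.22 under library size only and RLE factors. An exchange of both labels cannot be told apart from the labels as given: the correlation with the replicated comparison across genes was higher by 0.0940 for the library labelled high, but the dose of the replicated set is not in the labels, so its sign decides nothing.

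The 6 libraries of the replicated set allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3803 genes, with 1 split, the real one, giving as many and 1 gene as the highest count of the other splits. For lists camera gave 8 in the real split, again reached by 1 split, and 2 to 4 in each of the others. At the preset correlation camera thus called lists also in splits that mix the groups. Over both sets 2767 genes were called in the real split and at most 1282 in the other splits within the sets. Thus 1 of 60 splits gave as many. That share counts the libraries as independent, and the labels do not say that they were separate cultures, so chance is not excluded.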

How the results depend on the processing

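The settings without ribosomal RNA rows or without both number-1 libraries, and in the dose set thinning and RLE factors, were tests chosen after the data had been seen. Limma on log2(TPM + 1) called 964 genes (530 higher, 434 lower), on log2(TPM + 0.1) 910 (501 and 409), and on log2(TPM + 1) with no filter 204 (112 and 92). Of the HIF genes singled out in advance these called 4, 4 and 3, and the cause was not tested. By construction, an adjusted p under 0.01 in edgeR left 2049 genes (1062 and 987) and a fold of at least 1.5 left 760 (294 and 466). Other scalings, filters, DESeq2 and voom gave 3671 to 3879 genes, leaving out each library 2571 to 3980, and leaving out both number-1 libraries 3481. Of 25 lists, 2 passed with an estimated correlation and 14 by fry, which asks another question. Lists called by fry and not by camera were glycolysis, ER chaperones (fry adjusted p = 0.0382) and G2 and M phase (0.0235), all lower. DNA replication, p53 targets, epithelial and mesenchymal genes and fibroblast markers (fry adjusted p = 0.00534) were called higher by fry alone. Ribosomal proteins lost their call by fry (adjusted p = 0.305). With all 9 libraries the log2 fold change of SLC7A11 became 0.22 and that of APOH -0.0724, the signs reversed, and the cause was not tested. Over all settings, values of named genes kept their side of the threshold 2536 times, lost the call 230 times and gained it 17 times. The first count includes changes of sign where neither value passed.

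With the replicate number as a block, edgeR called 4436 genes, and the oxidative phosphorylation list passed (camera adjusted p = 0.0215). Deviations of libraries with the same number correlated at 0.085, 0.052 and -0.048, and not every library correlated best with its own number, so the libraries were not treated as paired.

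In the dose set a minimum of 100 counts left 43 genes at least 2-fold higher and 182 lower for high, 234 and 503 for low, and 150 and 93 for high over low, where fewer genes were compared. On log2(TPM + 1), which shrinks low genes, 45 were higher and 104 lower for high, 340 lower for low, and 91 and 108 for high over low. List medians near 0 changed sign. Only those whose size had been above the spread between replicated libraries are given here, and smaller ones are left out. Over all lists and settings, 251 medians stayed within that spread, 89 moved beyond it and 10 changed sign in this way. With library size only ER chaperones for high became 0.00118, p53 targets for high 0.00472 and interferon genes for low 0.0584. That scaling raised the median of all genes by 0.0646 for high and 0.133 for low, so these changes of sign say nothing on the lists. On log2(TPM + 1) ER chaperones for high became 0.0414, p53 targets 0.0462, immediate early genes 0.00329 and interferon genes 0.00442, and for low interferon genes 0.0590, oxidative phosphorylation 0.0199 and epithelial and mesenchymal genes 0.0144; the cause was not tested. Of genes called higher in the replicated set, 84.8% were higher for high and 80.6% for low with library size only, and 87.2% and 81.5% on log2(TPM + 1). Of those called lower, 72.2% and 63.7% were lower with library size only, and 67.0% and 61.7% on log2(TPM + 1). Of genes lower at an adjusted p under 0.01 in edgeR, 82.3% and 78.3% were lower, and of those called higher without both number-1 libraries 69.1% were higher for low. Depth limits genes with few counts, such as the deiminase genes.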

Other observations

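The lists of metallothionein, tubulin, NODAL and TGF-beta, and BMP genes, and the tests on them, those without shared genes or without single libraries included, were chosen after the genes with the largest changes had been seen.

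Genes that answer BMP signals were lower in the dose set. ID1, an inhibitor of DNA binding, had log2 ratios of -1.75 for high and -2.98 for low, ID2 of -1.08 and -1.55, and SMAD6, an inhibitory SMAD gene, of -1.04 and -1.17. HAMP and ATOH8, also known BMP targets, were among the lowest ratios there, though HAMP stood at 0.4 CPM at most in the DMSO replicates. In the replicated set ATOH8 was called higher, at 0.38 (edgeR adjusted p = 0.0442), a call that ended when each library was left out in turn (adjusted p from 0.0555 to 0.139). The list of 8 had medians of -1.06 and -1.06. In the replicated set its median was 0.22 and it did not pass (camera adjusted p = 0.10, with 4 genes higher and 2 lower), with ID1 at -0.27 and SMAD6 at 0.45. The call of ID2, one of the lower genes, ended without DMSO replicate 2 (edgeR adjusted p = 0.0515), DMSO replicate 3 (adjusted p = 0.0617), DHE replicate 2 (adjusted p = 0.0636) or DHE replicate 3 (adjusted p = 0.0704).

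The rise of CER1 in the replicated set led to the hypothesis that targets of NODAL and TGF-beta rose together. Of 11 tested genes in a list that left out CER1, LEFTY2, TGFB2 and THBS1 among others, 6 rose and none fell, with a median of 0.25 (camera adjusted p = 3.07e-04, and p = 0.0555 for camera with an estimated correlation). NODAL itself (-0.39, edgeR adjusted p = 0.661) and LEFTY1 (0.10, adjusted p = 0.488) were among the members that did not pass. Of the 6 that rose, 3 (SMAD6, SMAD7 and BAMBI) are also in the BMP list, so they are not specific to NODAL and TGF-beta. Among the 8 genes left without them, 3 rose, with a median of 0.12 (camera p = 0.00854, and p = 0.118 with an estimated correlation). This is consistent with the hypothesis at the preset correlation only, and in the dose set the full list had medians of -0.45 and -0.95 in the opposite direction, and the list without the shared genes -0.06 and -0.50. The rise of TUBA1A was not shared by 14 other tubulin genes (median -0.04, camera adjusted p = 0.580), of which TUBB3 rose and TUBA4A and TUBB4A fell. For MT2A the test was void, since MT1X was the only other metallothionein gene tested (0.62, camera adjusted p = 0.580).

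In the fit of the difference between the sets, PDK1 differed by -0.64 (edgeR adjusted p = 0.0424) and ADM by -0.53 (edgeR adjusted p = 0.0440), replicated set minus dose set. These were the HIF genes singled out in advance that passed in it. ALB stood at 29720 CPM, scaled over all 9 libraries, in the DMSO library of the dose set and at 6372, 5829 and 5982 CPM in the DMSO replicates.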
